A study of Mus musculus with 11 samples.

How the data were processed

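The series holds coding-sequence read counts for mRNA and for ribosome footprints from primed mouse OT1 CD8 T cells. There are 6 RNA libraries, 3 unstimulated and 3 stimulated for 2 h with CD3/CD28 beads, and 5 footprint libraries, 3 unstimulated and 2 stimulated. A stimulated footprint replicate 1 is not among the samples and was not analysed here. Per the submitters' processing notes, reads were aligned with STAR 2.5 to mm10 (GRCm38). The deposited values are raw counts per gene over coding sequences, whole numbers with no normalization, for 21957 genes in each library. The series-wide table holds the same 241527 values as the files of the single libraries. The labels do not state the counting tool, the annotation release, the handling of strands or any read filter. It is therefore not known whether genes that overlap on opposite strands were counted apart. Ensembl identifiers were matched to symbols and positions with the NCBI annotation of GRCm38, which named 21838 of them and left 119 without a symbol.

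Library totals were 21658263 to 39346699 counts in RNA and 11136 to 23641 in footprints, 85433 footprints in all. A count of 0 allows up to 3 counts, which is 269, 206 and 197 CPM (counts scaled to library size) in the unstimulated footprint libraries and 144 and 127 in the stimulated ones. These limits and all intervals cover counting error only. In simulated data of the same size and depth, edgeR recovered 71.6, 84.8 and 91.0% of tested genes changed 2-fold, 4-fold and 8-fold in RNA, with 5 false calls of 170, and 33.3, 88.6 and 100% in footprints, with 2 of 81. For efficiency it recovered 26.1, 91.7 and 100%, with 9 false calls of 94. The simulation drew each gene independently, with no shift shared by many genes of a library. Its false calls therefore do not cover such shifts in the real libraries.

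Each assay was tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM scaling and edgeR's filter on low counts (minimum count 10, minimum total 15). Translational efficiency was tested as the interaction of assay and stimulation in 1 model over all 11 libraries, with TMM factors within each assay, for genes that passed the filter in both. Adjusted p-values are Benjamini-Hochberg over the genes tested, with a threshold of 0.05. Levels are TMM-scaled CPM, and logarithms used a prior count of 2. All tests were two-sided. The comparisons, their tests, 35 gene lists with 1084 genes and the alternatives were set before the data were examined. Lists with at least 5 tested members were tested with camera in limma 3.58.1, with a preset correlation of 0.01 between genes, and again with an estimated correlation and with fry. The p-values of a comparison's lists were adjusted together, 34 lists in RNA and 13 each in footprints and efficiency. A gene is called adjusted over the list alone when its p passes after adjustment over that list's members.

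The genes named follow a rule. For each comparison they are the 10 most raised and 10 most lowered genes that passed, with at least 10 CPM in the higher group and no overlap between the groups' libraries (for efficiency at least 10 CPM in RNA and 5 CPM in footprints). Up to 4 members per list that passed were added, or the 2 most abundant where none passed, and 21 genes named in every case: Ifng, Tnf, Il2, Myc, Cd69, Il2ra, Il2rb, Ifngr1, Notch1, Egr1, Nr4a1, Irf4, Gzmb, Eef1a1, Eef2, Psat1, Shmt2, Atf4, Klf2, Cd8a and Actb. Other genes named, such as Ccl3, Ccl4, Ncl and Ddx21 in RNA, Cd4, Foxp3 and Cd40lg, or Notch1, Ncl, Rps3 and Ifng for efficiency, were chosen after their values were seen or come from the rule for another comparison. Ezr passed for efficiency and is outside the rule because its libraries overlap.

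Counts of a list's members were also summed per library and fitted with edgeR as 1 row per list, beside sums over 67 histone genes and over the RNA-raised and RNA-lowered genes. This step and the restriction to genes of at least 10 CPM were chosen after seeing the data. A measure of background was taken as the counts of 1515 olfactory, vomeronasal and defensin genes.

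Alternatives were DESeq2 1.42.0, limma voom, RLE scaling, library totals without TMM, scaling without ribosomal protein genes, no filter, a filter at a mean of 50 counts per group, an adjusted p of 0.01, replicate number as a block, each library left out in turn, and RNA counts thinned to the median footprint total of 15237 (seed 20) with stimulated replicate 1 left out. Chosen after seeing the data were a background covariate, scaling on genes of at least 10 CPM, scaling without 4 genes (Gm10800, Gm10801, Gm20594 and Lars2), and leaving out the 3 RNA libraries with the most background. DESeq2 was run without edgeR's filter, on 21427 genes in RNA, 10647 in footprints and 10636 for efficiency. Of the 1084 list genes, 12 had no entry of their own in the files and were left out.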

Results

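The labels describe primed OT1 cells, CD8 T cells that carry a transgenic receptor for an ovalbumin peptide, in an unstimulated state (T0) or activated for 2 h. The activating beads carry antibodies against CD3 and CD28, and all cells were then treated with cycloheximide for 10 min. Messenger RNA was measured in 3 unstimulated and 3 stimulated libraries, and ribosome footprints, the mRNA fragments protected by translating ribosomes, in 3 unstimulated and 2 stimulated libraries. The series design addresses how mRNA and its translation change in CD8 memory T cells within 2 h of activation. All positions are on GRCm38, and log2 changes are stimulated minus unstimulated with their standard error. The labels do not say whether replicates are separate cultures or animals, so each p-value measures only the spread between samples.

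In the RNA, genes for effector cytokines rose most among the known activation genes. Il2 (chromosome 3, 37120713 to 37125954), the T cell growth factor, went from 3.62 ± 0.418 to 215 ± 45.4 CPM (counts scaled to library size, mean ± SD, n = 3 per group). This was a 59.1-fold rise (log2 change 5.89 ± 0.25, adjusted p = 4.3e-07). Ifng (chromosome 10, 118441046 to 118445894), which encodes interferon gamma, went from 44.0 ± 4.11 to 1680.2 ± 267 CPM, 38.1-fold. Csf2, which encodes the growth factor GM-CSF, rose 58.7-fold from 2.46 ± 0.191 to 144 ± 19.8 CPM. Tnf, which encodes tumour necrosis factor, was already at 146 ± 11.6 CPM in unstimulated cells and reached 1112 ± 269 CPM (7.61-fold, adjusted p = 3.3e-05). In the other direction, Bcl6, a transcriptional repressor, fell from 75.9 ± 2.41 to 9.95 ± 1.45 CPM, a 7.63-fold decrease (log2 change -2.93 ± 0.17, adjusted p = 2.3e-06). S1pr1, the receptor that guides T cells out of lymphoid organs, fell 3.35-fold from 189 ± 3.49 to 56.3 ± 10.7 CPM.

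Of 18886 genes tested in RNA with edgeR, 1560 changed at an adjusted p under 0.05, 677 higher and 883 lower in stimulated cells, and 326 of the higher and 209 of the lower genes changed at least 2-fold. Among the effector cytokines and chemokines, 19 of 36 tested genes rose, 2 fell and 15 did not pass (25 and 2 adjusted over the list alone), with a median log2 change of 1.78. Camera gave adjusted p = 4.9e-55 for these genes, and adjusted p = 0.330 with an estimated correlation. Fry gave adjusted p = 0.0199. Among genes of at least 10 CPM, a restriction chosen after the data were seen, camera with an estimated correlation gave adjusted p = 0.0184. The chemokine genes Ccl3 (2.85), Ccl4 (2.52) and Xcl1 (2.53) rose beside Il2 and Csf2, and Il16 fell (-1.37). The death ligand gene Tnfsf10 also fell (-0.65), a call lost without unstimulated replicate 1 (0.0905) or 3 (0.112), or stimulated replicate 1 (0.113) or 2 (0.115).

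Of 44 immediate early and activation transcription factors, 27 rose, 2 fell and 15 did not pass (28 and 3 adjusted over the list alone). Their median was 0.93 (camera adjusted p = 5.9e-18, adjusted p = 0.980 with an estimated correlation). Irf8 (3.50 ± 0.25) and Irf4 (1.76 ± 0.23), members of the interferon regulatory factor family, rose, as did Ier3 (3.04) and the orphan nuclear receptors Nr4a1 (1.45) and Nr4a3 (1.39). Myc, which drives growth and ribosome production, went from 211 ± 2.497 to 748 ± 171 CPM (1.83 ± 0.22, adjusted p = 5.5e-04). Egr1 rose 1.95-fold (0.96 ± 0.21, adjusted p = 0.0177), which was lost without unstimulated replicate 1 (0.0760) or 3 (0.162), or stimulated replicate 1 (0.0923) or 2 (0.253). Nr4a2 (1.21) was lost without stimulated replicate 2 (0.0771), and Junb (1.12) without unstimulated replicate 3 (0.0590), or stimulated replicate 2 (0.112). The fall of Ikzf2 (-0.69) was lost without unstimulated replicate 1 (0.154) or 3 (0.169), or stimulated replicate 1 (0.202) or 2 (0.183).

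Most genes of ribosome biogenesis, which encode the nucleolar machinery that transcribes and processes ribosomal RNA, rose. Of 56 genes, 35 rose and none fell (54 and 0 adjusted over the list alone). The median was 0.82 (camera adjusted p = 1.4e-25, adjusted p = 0.980 with an estimated correlation). Polr1b, a subunit of RNA polymerase I, rose from 59.6 ± 6.62 to 185 ± 48.0 CPM (1.63 ± 0.22), and Nop16 changed by 1.44. Ncl (1.04) was lost without unstimulated replicate 3 (0.125), or stimulated replicate 1 (0.101) or 2 (0.144). Ddx21 (0.84) was lost without unstimulated replicate 1 (0.151) or 3 (0.314), or stimulated replicate 1 (0.213) or 2 (0.319). In contrast, none of the 81 cytosolic ribosomal proteins changed by edgeR in this test (0 also adjusted over the list alone, camera adjusted p = 0.962, median 0.10 by TMM scaling). The sum of their counts went from 3.94 ± 0.400 to 3.68 ± 0.517% of all RNA counts, a log2 change of 0.09 that turned to as low as -0.25 under other scalings. The 4 genes Gm10800, Gm10801, Gm20594 and Lars2 took 4.09 to 14.9% of unstimulated and 12.8 to 25.0% of stimulated RNA counts. This lowers the share left to all other genes. Among genes of at least 10 CPM, a restriction chosen after the data were seen, 56 of the 81 passed as higher and none as lower (camera adjusted p = 0.0608). The other mRNAs with a 5' terminal oligopyrimidine tract (TOP), the motif through which growth signals control translation of ribosomal and elongation factor mRNAs, were tested as a list of their own. By edgeR 0 of 24 genes changed (0 adjusted over the list alone, camera adjusted p = 0.311). Among genes of at least 10 CPM, 20 of these 24 passed as higher and none as lower, with a median of 0.30 (camera up, adjusted p = 0.0155, adjusted p = 0.497 with an estimated correlation). With that restriction the RNA sum rose by 0.18 ± 0.05 for ribosomal proteins (adjusted p = 0.00415) and by 0.25 ± 0.03 for the other TOP mRNAs (adjusted p = 4.2e-05). In the 13 other alternatives neither sum passed. By edgeR on all genes, Eef1a1 was at 0.08 and Eef2 at 0.01.

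Smaller parts of several signalling lists changed. Among translation initiation factors, 5 of 34 rose and 1 fell (5 and 1 adjusted over the list alone, camera up, adjusted p = 0.0137, adjusted p = 0.990 with an estimated correlation). The list's call was lost without unstimulated replicate 2 (0.546) or 3 (0.0769), or stimulated replicate 2 (0.228) or 3 (0.0742). Eif1a (1.07) was lost without unstimulated replicate 3 (0.0990), or stimulated replicate 1 (0.0682) or 2 (0.135). Eif2b3 (0.89) was lost without unstimulated replicate 3 (0.0939), or stimulated replicate 1 (0.0892) or 2 (0.149), and the fall of Eif4ebp2 (-0.88) without stimulated replicate 2 (0.0514). In the NF-kappaB pathway, 6 of 29 rose and 1 fell (10 and 2 adjusted over the list alone, camera up, adjusted p = 0.00440, adjusted p = 0.990 with an estimated correlation). The most raised were Nfkbid (2.40 ± 0.23) and Nfkbiz (1.55). The pathway's call was lost without unstimulated replicate 2 (0.338), or stimulated replicate 2 (0.0732) or 3 (0.0742). Of 37 negative feedback regulators, 12 rose and 6 fell (15 and 8 adjusted over the list alone, camera up, adjusted p = 0.00104, adjusted p = 0.990 with an estimated correlation). Cish (2.99 ± 0.23), an inhibitor of cytokine signalling, and Spry1 (2.95 ± 0.22), an inhibitor of the MAP kinase pathway, rose, while the RNA-binding protein gene Zfp36l2 (-1.25) and the phosphodiesterase gene Pde4d (-1.22) fell. The feedback list's call was lost without unstimulated replicate 2 (0.177). Of 26 genes for heat shock and cytosolic chaperones, 3 rose (3 adjusted over the list alone, camera up, adjusted p = 0.00974, adjusted p = 0.990 with an estimated correlation). This list call was lost without unstimulated replicate 2 (0.338), or stimulated replicate 2 (0.104) or 3 (0.0619). Hspa1a (2.51) was lost without unstimulated replicate 1 (0.0535) or 3 (0.126), or stimulated replicate 1 (0.0608) or 2 (0.0886). Hspa1b (1.90) was lost without unstimulated replicate 1 (0.119) or 3 (0.176), or stimulated replicate 1 (0.0692) or 2 (0.178) or 3 (0.0681).

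Parts of the lists for the resting state and the cell cycle fell after stimulation. Of 34 resting and quiescence genes, 15 fell, 1 rose and 18 did not pass (18 and 2 adjusted over the list alone, camera adjusted p = 4.5e-19, adjusted p = 0.980 with an estimated correlation). The glucocorticoid-induced gene Tsc22d3 (-1.98 ± 0.20), Arrdc3 (-1.76) and the cell cycle inhibitor gene Cdkn1b (-1.31) fell. Klf2, a regulator of T cell trafficking, fell as well (44.0 ± 4.43 to 21.2 ± 5.55 CPM, -1.05 ± 0.19, adjusted p = 0.00625), and the rise of Slfn2 (0.80) was lost without unstimulated replicate 1 (0.189) or 3 (0.342), or stimulated replicate 1 (0.265) or 2 (0.334). Of 38 genes for cell cycle S and G2/M, 14 fell, none rose and 24 did not pass (27 and 0 adjusted over the list alone). Camera gave this list adjusted p = 3.5e-21, and adjusted p = 0.980 with an estimated correlation. E2f2 (-1.28) and Ccnb2 (-1.03) fell most. Among cytokine and Notch receptors, 12 of 40 fell and 3 rose (17 and 4 adjusted over the list alone, camera adjusted p = 2.3e-06, adjusted p = 0.990 with an estimated correlation). Il2ra, the high-affinity interleukin-2 receptor subunit, rose 2.49-fold (1.32 ± 0.21) and Il1rl1 rose by 1.33. Ifngr1, a subunit of the interferon gamma receptor, fell from 947 ± 73.3 to 373 ± 90.4 CPM (-1.34 ± 0.22, adjusted p = 0.00409), and S1pr4 fell by 1.48. Il2rb (-0.01, adjusted p = 0.984) and Notch1 (0.02, adjusted p = 0.945) did not pass.

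A further 6 lists, several of them for metabolism and protein folding, were called lower by camera. Of 33 genes for cholesterol and fatty acid synthesis, 5 fell (8 adjusted over the list alone), among them Fads1 (-0.99), with an adjusted p of 2.4e-05 by camera. Endoplasmic reticulum chaperones and the unfolded protein response had 4 of 26 lower (5 adjusted over the list alone, camera adjusted p = 0.000110). The calls of Herpud1 (-1.03) and Sdf2l1 (-0.76) were lost without stimulated replicate 2 (0.0531) for the former and without unstimulated replicate 3 (0.0754), or stimulated replicate 1 (0.0857) or 2 (0.0834) for the latter. In the list for the T cell receptor complex and proximal signalling, 2 of 34 fell (4 adjusted over the list alone, camera adjusted p = 0.000787), the adaptor gene Sla2 (-1.47) and Pag1 (-1.20), and Cd8a did not pass (-0.01). Nuclear encoded genes of oxidative phosphorylation were called lower as a list with 0 of 76 genes passing by edgeR (0 adjusted over the list alone, camera adjusted p = 0.00970). For MHC class I and antigen presentation, 1 of 18 fell (1 adjusted over the list alone, camera adjusted p = 0.000272): Pdia3 (-0.76), lost without unstimulated replicate 1 (0.147) or 3 (0.190), or stimulated replicate 1 (0.147) or 2 (0.211). In the actin cytoskeleton list, 1 of 35 fell (1 adjusted over the list alone, camera adjusted p = 0.000295): Flna (-1.02), lost without unstimulated replicate 3 (0.0627), or stimulated replicate 2 (0.0531). Actb did not pass (-0.26, adjusted p = 0.419). For each of these 6 lists, adjusted p = 0.990 with an estimated correlation. Among genes of at least 10 CPM, the camera call of all 6 was lost: cholesterol synthesis (0.0608), endoplasmic reticulum (0.0628), T cell receptor complex (0.129), MHC class I (0.0659), actin (0.140) and oxidative phosphorylation (0.872). In the last, 11 genes rose and 12 fell there, with a median of 0.02.

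Apart from 1 list of cell type markers given below, the remaining lists were not called by camera. Of 47 activation, costimulatory and inhibitory receptors, 13 rose and 7 fell (17 and 11 adjusted over the list alone, camera adjusted p = 0.962), with a median of -0.19 and a mean of 0.13. Sema7a (2.25) and Cd83 (2.10) rose, and Cd28 (-1.38) and the integrin gene Itgb7 (-1.36) fell. Cd69, an early activation marker, rose from 1005 ± 61.8 to 1991 ± 432 CPM (0.99 ± 0.22, adjusted p = 0.0168), lost without unstimulated replicate 1 (0.0686) or 3 (0.217), or stimulated replicate 1 (0.0785) or 2 (0.207). Among cytotoxic granule genes, 1 of 24 rose and 1 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.396), with a median of -0.06 and a mean of 0.11. Gzmb did not pass (-0.46, adjusted p = 0.237). The raised Stx11 (0.96) was lost without unstimulated replicate 3 (0.0651), or stimulated replicate 1 (0.0537) or 2 (0.115), and the lowered Ctsd (-0.93) without unstimulated replicate 3 (0.0553), or stimulated replicate 1 (0.0775) or 2 (0.0838). Of 27 G1 cyclins and growth control genes, 5 rose and 2 fell (6 and 3 adjusted over the list alone, camera adjusted p = 0.829). The survival gene Bcl2l1 (2.35 ± 0.22) and the kinase gene Pim3 (1.54) rose. The lowered death gene Bcl2l11 (-1.05) was lost without stimulated replicate 2 (0.0515). Of 42 interferon-stimulated genes, 7 rose and 2 fell (8 and 3 adjusted over the list alone, camera adjusted p = 0.311, and 0.0155 up among genes of at least 10 CPM, 0.518 there with an estimated correlation). Iigp1 (1.69) and Gbp5 (1.45) rose. The lowered Ifit2 (-0.84) was lost without stimulated replicate 2 (0.0709), and the lowered Mx1 (-0.69) without unstimulated replicate 1 (0.0593) or 3 (0.108), or stimulated replicate 1 (0.0524) or 2 (0.0968).

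In serine synthesis and one-carbon metabolism, 4 of 24 rose and 1 fell (4 and 2 adjusted over the list alone, camera adjusted p = 0.909). Mat2a (1.08) was lost without unstimulated replicate 3 (0.103), or stimulated replicate 1 (0.0521) or 2 (0.141), and Slc25a32 (0.90) without unstimulated replicate 3 (0.124), or stimulated replicate 1 (0.111) or 2 (0.157). Psat1 (0.25) and Shmt2 (0.26), enzymes of that pathway, did not pass. In the ATF4 and amino acid response, 1 of 31 rose and 3 fell (3 and 3 adjusted over the list alone, camera down, adjusted p = 0.351), with a median of 0.15 on the other side of 0. Chac1 (-2.03) and Ddit4 (-1.14) fell, the rise of Atf5 (0.93) was lost without unstimulated replicate 1 (0.203) or 3 (0.231), or stimulated replicate 1 (0.177) or 2 (0.275), and Atf4 itself did not pass (0.42). In glycolysis and glucose transport, 1 of 22 rose, the hexokinase gene Hk2 (2.83-fold), and none fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.962, median -0.06 and mean 0.12). In the proteasome list, 1 of 31 rose (0 adjusted over the list alone, camera adjusted p = 0.959): Psmd7 (0.63), lost without unstimulated replicate 1 (0.273) or 3 (0.383), or stimulated replicate 1 (0.376) or 2 (0.405). The 13 mitochondrially encoded proteins had 0 counts in all 11 libraries and were not tested.

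The largest RNA changes of all included genes outside the lists. Lars2 (chromosome 9, 123366927 to 123462675), which encodes the mitochondrial leucyl-tRNA synthetase, went from 82.1 ± 43.9 to 46396 ± 8087 CPM (9.14 ± 0.49, adjusted p = 1.3e-06). It took between 3.88 and 4.90% of all counts in the stimulated RNA libraries, with a count of 0 in both stimulated footprint libraries. Rps6ka2 (7.86), 1810010D01Rik (7.39), Cep112 (6.53), Hoxd11 (6.51), Emp2 (6.04), Sox12 (5.91) and Fam20a (5.59) followed. H60b, a ligand of the receptor NKG2D, had the largest decrease (-2.96 ± 0.26), and Nod1 (-1.91), Fam196b (-1.84), Gramd3 (-1.66) and Rap1gap2 (-1.66) were also among the 10 most lowered.

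Markers of other cell types were measured the same way. Of the markers, 1 of 15 for B cells rose (camera adjusted p = 0.345), and 1 of 15 for macrophages and monocytes fell (0.959). For dendritic cells 2 of 11 rose (0.111), for neutrophils 1 of 13 rose (0.0592), and for erythroid cells 1 of 6 fell (0.909). For NK cells and innate lymphocytes none of 9 passed by edgeR (0.598), and for fibroblast and stromal cells 1 of 16 fell (0.424). The list for CD4 and regulatory T cells had 3 of 9 raised (0.00881, adjusted p = 0.990 with an estimated correlation). The same counts held when adjusted over the list alone. Ikzf4 (2.23 ± 0.18) and Cd40lg (1.07) were among the raised CD4 and regulatory T cell genes, while Cd4 (0.88) and Foxp3 (0.04) did not pass. Batf3 (1.85), Ngp (3.79) and Ms4a6c (-1.11) passed in every fit without 1 library. Cd74 (0.99) was lost without stimulated replicate 2 (0.0715) and Zbtb46 (0.97) without stimulated replicate 2 (0.0605). Alas2 (-1.53) was lost without unstimulated replicate 1 (0.130) or 3 (0.159), or stimulated replicate 2 (0.105). Pecam1 (-0.86) was lost without unstimulated replicate 3 (0.0625), or stimulated replicate 1 (0.0857) or 2 (0.0900). Medians of these marker lists lay between 0.68 and 1.01, apart from neutrophils at 1.29. The median was 1.25 over 1261 olfactory, vomeronasal and defensin genes used as a measure of background, of which 1 passed. Background stood at 1883 CPM in unstimulated replicate 2, 2753 in stimulated replicate 1 and 2026 in stimulated replicate 2, against 299.6, 406 and 685 in unstimulated replicates 1 and 3 and stimulated replicate 3.

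**Figure D1:**
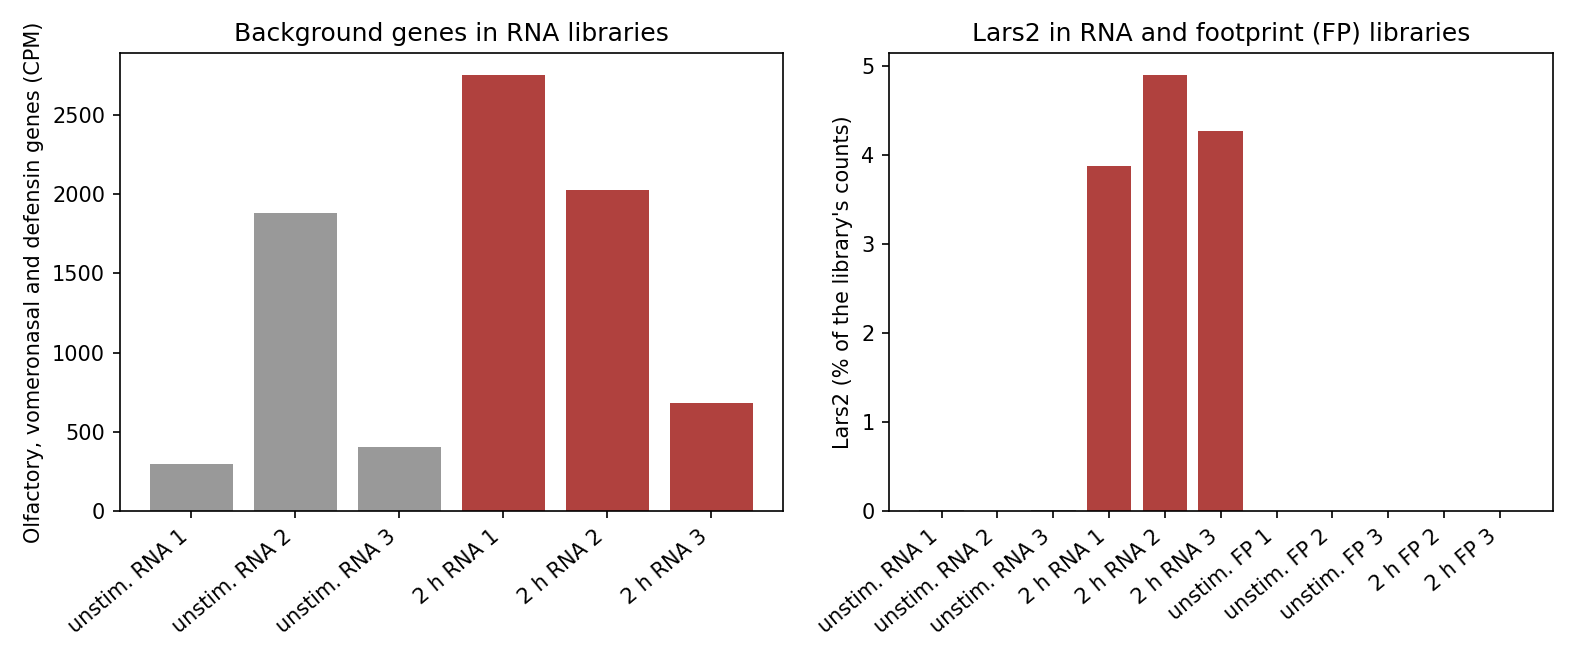
Left, library-size scaled counts (CPM) of olfactory, vomeronasal and defensin genes in the 6 RNA libraries, from 299.6 to 2753. Right, Lars2 as a percentage of counts in all 11 libraries, between 3.88 and 4.90% in the 3 stimulated RNA libraries, with grey bars for unstimulated and red bars for stimulated libraries.

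The count of 1560 genes depended on which libraries entered. Without unstimulated replicate 1, 2 or 3 it was 917, 13024 or 646, and without stimulated replicate 1, 2 or 3 it was 789, 583 or 5255. The higher and lower split of 677 and 883 became 363 and 2466 with DESeq2, 1867 and 1520 with limma voom, and 410 and 1007 with no filter on low counts. With RLE scaling it was 334 and 1364, and with library totals 1005 and 4215. The median log2 change of all genes, 0.39, became 0.19 with RLE scaling and 0.22 with library totals. Among the 8494 genes of at least 10 CPM, tested after the data were seen, 6228 changed, 3138 higher and 3090 lower, including 1394 of the 1560 in the same direction. Most of these changes were small: 293 of the higher and 111 of the lower genes changed at least 2-fold, with a median standard error of 0.051.

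Ribosome footprints of cytokine and activation genes rose as well. Ifng rose from 6 footprints over the 3 unstimulated libraries to 110 over the 2 stimulated ones (167 ± 129 to 2433 ± 614 CPM, 15.6-fold, log2 change 3.97 ± 0.55, adjusted p = 2.2e-10). Footprints on Ccl4, a chemokine gene, went from 38 to 172 (2.01 ± 0.30, adjusted p = 1.9e-09) and those on Nr4a1, an immediate early nuclear receptor gene, from 50 to 158 (1.49 ± 0.28, adjusted p = 8.3e-06). Footprints fell on histone genes, such as Hist1h1d, a linker histone gene (192 to 72, -1.58 ± 0.22, adjusted p = 2.2e-10), and on Actb, which encodes beta-actin (475 to 355, -0.59 ± 0.09, adjusted p = 5.3e-07).

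The footprint libraries hold 11136 to 23641 counts each, so 256 genes could be tested, and 24 of them changed, 15 higher and 9 lower in stimulated cells. Among effector cytokines and chemokines, 5 of 6 tested genes rose and none fell (5 and 0 adjusted over the list alone, camera adjusted p = 3.7e-07, adjusted p = 0.362 with an estimated correlation). These were Ifng, Tnf (2.73 ± 0.62), Ccl3 (2.15), Ccl4 and Xcl1 (1.23). Of 11 immediate early and activation transcription factors, 5 rose and none fell (6 and 0 adjusted over the list alone, camera adjusted p = 8.2e-06, adjusted p = 0.362 with an estimated correlation). They were Nr4a1, Nr4a2 (2.53), Nr4a3 (1.90), Irf8 (2.04) and Junb (1.67). Of 7 other TOP mRNAs, 2 rose and none fell (4 and 0 adjusted over the list alone, camera adjusted p = 0.00766, adjusted p = 0.488 with an estimated correlation). The elongation factor gene Eef2 rose (45 to 134 footprints, 1.36 ± 0.31, adjusted p = 2.3e-04). Rack1, which encodes a protein of the small ribosomal subunit, also rose (41 to 109, 1.25 ± 0.35, adjusted p = 0.00498). Of 4 ribosomal protein genes with enough footprints, 1 rose, Rps3 (1.38, 1 adjusted over the list alone). In the NF-kappaB pathway 1 of 4 rose, Nfkbid (3.32), and among negative feedback regulators 1 of 5, Cish (2.57, camera adjusted p = 0.0892, 1 adjusted over the list alone in either list). Of 15 actin cytoskeleton genes, 1 fell, Actb (1 adjusted over the list alone, camera adjusted p = 0.0364, adjusted p = 0.488 with an estimated correlation).

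Several calls were lost when 1 footprint library was left out. Tnf was lost without unstimulated replicate 2 (0.0554), or stimulated replicate 3 (0.680), and Ccl3 without unstimulated replicate 2 (0.0803), or stimulated replicate 3 (0.460). Xcl1 was lost without unstimulated replicate 2 (0.128), or stimulated replicate 2 (0.0522) or 3 (0.335), and Nr4a2 without unstimulated replicate 2 (0.0788), or stimulated replicate 2 (0.905) or 3 (0.784). Nr4a3 was lost without stimulated replicate 3 (0.159), and Irf8 without unstimulated replicate 2 (0.209), or stimulated replicate 3 (0.343). Junb was lost without unstimulated replicate 2 (0.128) or 3 (0.0538), or stimulated replicate 2 (0.0909) or 3 (0.343), and Eef2 without unstimulated replicate 2 (0.112), or stimulated replicate 3 (0.159). Rack1 was lost without stimulated replicate 2 (0.108) or 3 (0.343), and Rps3 without unstimulated replicate 1 (0.190) or 2 (0.292), or stimulated replicate 2 (0.0678) or 3 (0.857). Nfkbid was lost without stimulated replicate 2 (0.0731) or 3 (0.159), and Cish without unstimulated replicate 2 (0.0597). The other TOP mRNAs as a list were lost without unstimulated replicate 3 (0.132), and the actin cytoskeleton list without stimulated replicate 3 (0.271). Ifng, Ccl4, Nr4a1, Hist1h1d, Hist1h1a, Hist2h4 and Actb were called in each of those 5 fits. The count of 24 was 15 (9 higher and 6 lower) without stimulated replicate 2 and 12 (4 higher and 8 lower) without stimulated replicate 3.

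Other lowered footprints were those of the endosomal sorting gene Vps37b (-2.48 ± 0.62), lost without stimulated replicate 2 (0.151), and of further histone genes. Hist1h1a (-1.44) and Hist2h4 (-1.34) fell. Hist1h2ak (-2.11) was lost without stimulated replicate 2 (0.0704) or 3 (0.460), and Hist4h4 (-1.20) without unstimulated replicate 1 (0.0750), or stimulated replicate 2 (0.147). Hist1h1b (-1.19) was lost without stimulated replicate 3 (0.125), and Hist1h1c (-0.97) without stimulated replicate 2 (0.0704). Histone paralogs share reads, so single members are not separate measurements.

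No member of the other lists passed by edgeR in footprints, where 54 genes had an unadjusted p under 0.05. DESeq2, run over 10647 genes without edgeR's filter, called 11 (7 higher and 4 lower). Limma voom on the 256 genes called 23 (10 higher and 13 lower). Adjusted over the list alone, 1 of 4 cytotoxic granule genes and 1 of 2 genes of growth control passed as higher. Camera gave adjusted p = 0.949 for the 7 activation, costimulatory and inhibitory receptors, 0.729 for the 9 genes of the T cell receptor complex, 0.949 for the 6 of the ATF4 response, and 0.881 for the 5 of oxidative phosphorylation. It gave 0.563 for the 5 endoplasmic reticulum chaperones and for the 6 heat shock genes, 0.995 for the 7 cell cycle genes and 0.949 for the 9 of MHC class I. Myc went from 45 to 86 footprints (0.76, adjusted p = 0.208), Notch1 from 9 to 38 (1.86, adjusted p = 0.125), neither of which passed. Cd69 (1.17), Irf4 (0.85), Egr1 (0.37), Gzmb (-0.12), Ifngr1 (-0.44), Il2rb (0.33) and Cd8a (-0.77) did not pass either. Il2 (2 to 42 footprints), Il2ra (10 to 22), Eef1a1 (8 to 29), Psat1 (10 to 32), Shmt2 (9 to 36), Klf2 (19 to 10) and Atf4 (4 to 3), summed over 3 unstimulated and 2 stimulated libraries, were not tested. They did not pass edgeR's filter on low counts, which looks at single libraries and not only at the sum.

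Summing footprints over each list, a step chosen after the data were seen, reached the groups whose members are too sparse for a test. Ribosomal protein mRNAs took 0.723 ± 0.0976% of unstimulated and 1.16 ± 0.0519% of stimulated footprints (log2 change 0.62 ± 0.13, adjusted p = 0.00415), higher in 2 of 2 stimulated libraries than in any unstimulated one. The other TOP mRNAs went from 0.761 ± 0.186 to 1.53 ± 0.0489% (0.96 ± 0.23, adjusted p = 0.00893). Cytokine and chemokine mRNAs went from 0.545 ± 0.185 to 1.77 ± 0.0212% (1.66 ± 0.26, adjusted p = 0.00158) and activation transcription factors from 1.04 ± 0.194 to 2.33 ± 0.0541% (1.11 ± 0.20, adjusted p = 0.00199). The sum over 67 replication-dependent histone genes, whose share of RNA counts was 2.62 ± 0.414% before and 1.33 ± 0.260% after stimulation, fell from 4.55 ± 0.772 to 2.19 ± 0.0253% of footprints (-1.11 ± 0.12, adjusted p = 0.000300). Ribosome biogenesis mRNAs rose from 0.877 ± 0.0407 to 1.34 ± 0.161% (0.56 ± 0.15, adjusted p = 0.0158), a call lost without unstimulated replicate 2 (0.121) or 3 (0.0516), or stimulated replicate 2 (0.0825). With replicate number as a block, the sums of ribosomal proteins (0.0564), other TOP mRNAs (0.0822) and ribosome biogenesis (0.0630) did not pass. Ribosomal protein genes and their processed pseudogenes share reads, and the share of these genes in unstimulated RNA was 5.45 times that in unstimulated footprints.

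**Figure D2:**
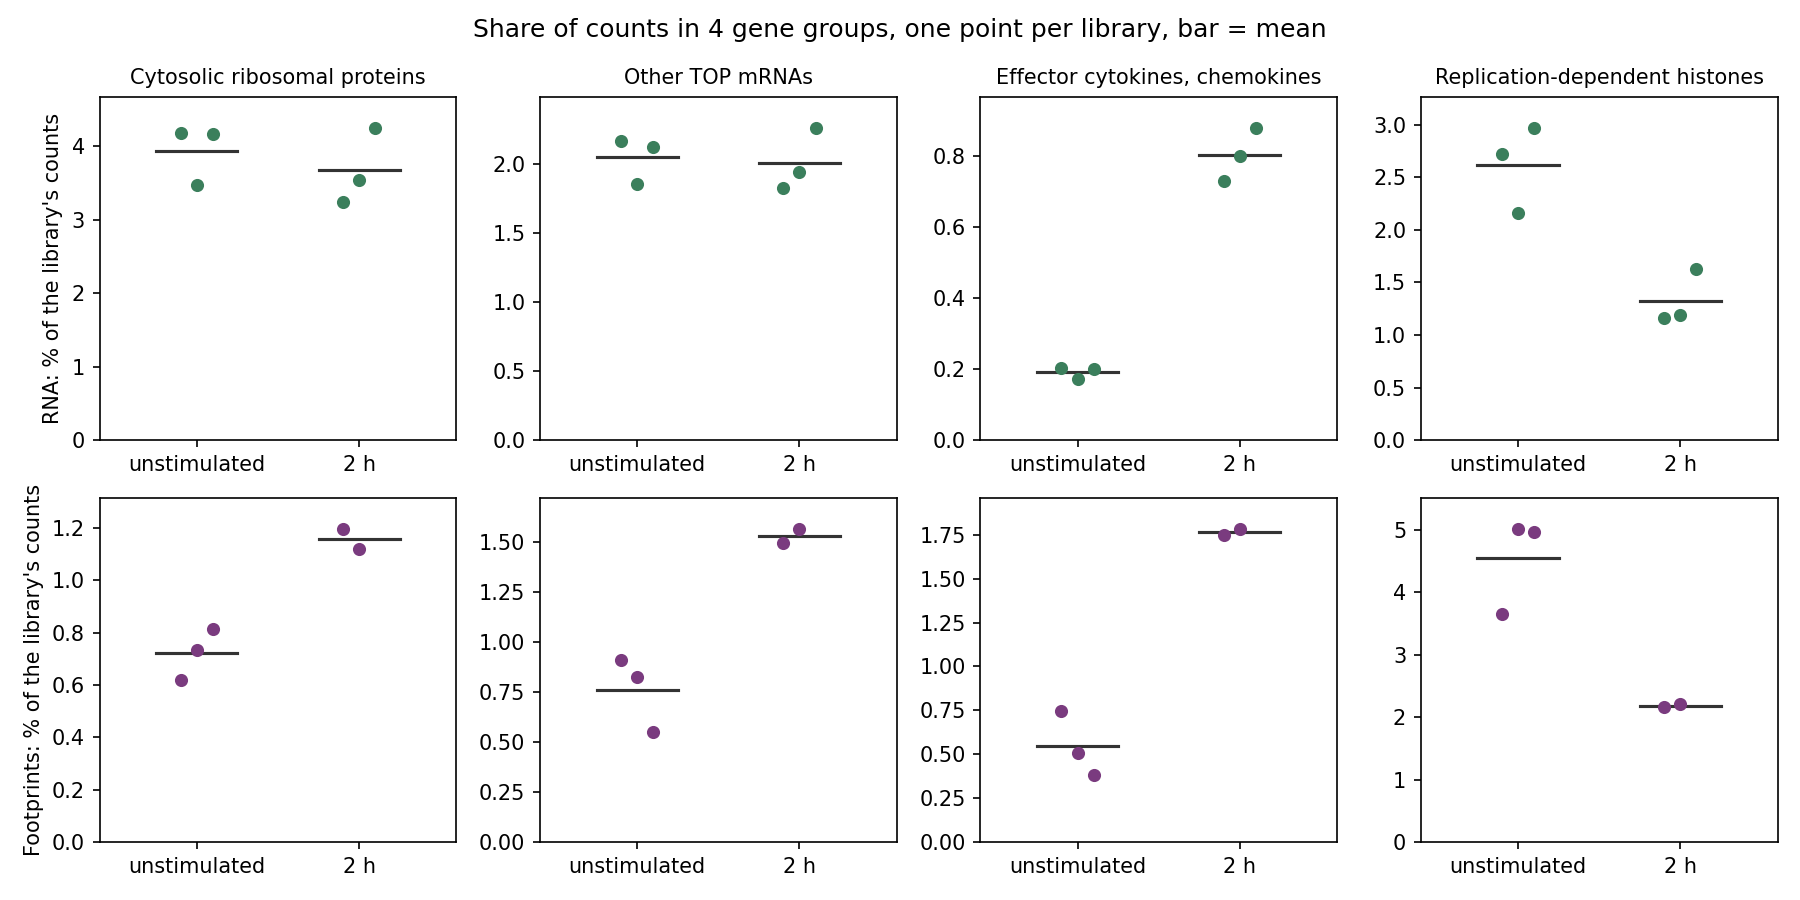
Share of each library's counts in 4 gene groups, in percent, with RNA in the upper and footprints in the lower row, 1 point per library and a bar at the group mean. Ribosomal protein footprints averaged 0.723% before and 1.16% after stimulation, while their RNA averaged 3.94 and 3.68%, a change whose sign depended on the scaling.

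Translational efficiency, the footprint change relative to the RNA change, shifted for 8 of 255 tested genes, 4 up and 4 down. Eef2, the elongation factor that moves the ribosome along the mRNA, gained 2.44-fold in footprints per RNA (log2 change 1.29 ± 0.30, adjusted p = 0.0309). Rack1 gained 2.08-fold (1.06 ± 0.28, adjusted p = 0.0458), while their RNA changes of 0.01 and 0.08 did not pass. Mcm4, a subunit of the replicative helicase (2.43 ± 0.65, adjusted p = 0.0458), and Tubb5, a beta-tubulin (0.90 ± 0.22, adjusted p = 0.0443), were the other genes with a gain. Losses were measured for Actb (-0.44 ± 0.10, adjusted p = 0.0309), Myc (-1.18 ± 0.32, adjusted p = 0.0458) and the chemokine gene Xcl1 (-1.39 ± 0.31, adjusted p = 0.0309). Ezr, which links actin to the membrane, also lost efficiency (-1.95 ± 0.52, adjusted p = 0.0458, 32 to 11 footprints, with overlapping libraries). For Myc and Xcl1 the RNA rose by 1.83 and 2.53 and the footprints by 0.76 and 1.23, of which the Myc footprint change did not pass. The joint model fits 1 spread per gene to both assays. Its common dispersion was 0.00235 over 255 genes, against 0.0582 in the footprint fit over 256 genes. The 0.171 of the RNA fit covers 18886 genes and is not a like comparison. Its median standard error over genes of at least 10 CPM was 0.406, below the 0.549 of footprints alone. Its p-values, also those of the list sums, may thus understate the footprint spread.

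Of 7 other TOP mRNAs, 2 rose in efficiency, Eef2 and Rack1, and none fell (4 and 0 adjusted over the list alone, camera adjusted p = 0.00394, adjusted p = 0.624 with an estimated correlation). That call was lost without unstimulated footprint replicate 3 (0.252). No other of the 13 lists passed. Effector cytokines had 1 of 6 lower, actin cytoskeleton 2 of 15 lower and cell cycle 1 of 7 higher (each camera adjusted p = 0.241 and the same count adjusted over the list alone). Activation transcription factors had 1 of 11 lower (0.714, 1 adjusted over the list alone). Adjusted over the list alone, 1 gene rose in each of ribosomal proteins, activation receptors, cytokine and Notch receptors and glycolysis, and 1 fell in each of ribosome biogenesis and fibroblast markers. Glycolysis and fibroblast markers had 1 tested gene each, Pfkp and Thy1, so their p-values are in effect unadjusted. Notch1 (1.77 ± 0.50, adjusted p = 0.0566), Ncl (-1.30, adjusted p = 0.0609), Rps3 (1.19, adjusted p = 0.0893) and Ifng (-1.36, adjusted p = 0.348) did not pass. In the list sums, footprints per RNA rose for ribosomal proteins (0.41 ± 0.12, adjusted p = 0.0245) and other TOP mRNAs (0.71 ± 0.16, adjusted p = 0.0104). They fell for ribosome biogenesis (-0.40 ± 0.09, adjusted p = 0.0104) and for cytokines (-0.67 ± 0.20, adjusted p = 0.0245). With library totals only, the ribosome biogenesis sum was at -0.04 (adjusted p = 0.897) and the cytokine sum at -0.33 (0.302). With footprints thinned to the smallest total they were at -0.19 (0.496) and -0.62 (0.0982). Leaving out the 3 background-rich RNA libraries left 1 stimulated RNA library, so only effects are given. Other TOP mRNAs were at 0.70 there, ribosomal proteins at 0.39, ribosome biogenesis at -0.39 and cytokines at -0.61, with wider standard errors. The ribosomal protein sum was lost without unstimulated footprint replicate 2 (0.0868), or stimulated footprint replicate 2 (0.0911) or 3 (0.0810). The cytokine sum was lost without unstimulated RNA replicate 2 (0.0504), stimulated RNA replicate 1 (0.0534) or stimulated footprint replicate 2 (0.0656). It did not pass with replicate number as a block (0.0522). Sums for the actin cytoskeleton (-0.27) and interferon-stimulated genes (-0.36) passed by TMM and were at 0.09 and 0.00 with library totals. The former was lost without any 1 of the 5 RNA libraries other than stimulated replicate 3, and both without stimulated footprint replicate 3 (0.0849 and 0.163). The latter was also lost without unstimulated footprint replicate 2 (0.0567), and neither passed with the block (0.0697 each). Without the 3 background-rich RNA libraries the actin and interferon sums were at -0.27 and -0.37. With footprints thinned the actin sum was lost (0.386).

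Each of the 8 single-gene calls of efficiency was lost without at least 1 library. Without unstimulated RNA replicate 1 or stimulated footprint replicate 3, edgeR called 0 genes. Without unstimulated RNA replicate 3, stimulated RNA replicate 1 or 2, unstimulated footprint replicate 3 or stimulated footprint replicate 2, it called 2, 4, 2, 3 and 1. With library totals 15 rose and 0 fell, as the median of all genes moved from -0.05 to 0.29. DESeq2, run over 10636 genes without edgeR's filter, gave 20 up and 9 down. These held 7 of the 8 edgeR calls in the same direction. Limma voom on the 255 genes called 0, with 54 genes at an unadjusted p under 0.05 by edgeR.

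Across the 255 genes tested in both assays, RNA and footprint log2 changes had Pearson's r = 0.710 and Spearman's rho = 0.636, as a description across genes, which are not independent replicates. All 24 genes called in footprints had the same sign in RNA, and 16 were called there too. Of the 49 genes called in RNA among the 255, 33 were not called in footprints, which does not show that they differed between the assays. Per-gene efficiency levels in unstimulated and stimulated cells had r = 0.797 across genes. Without stimulated footprint replicate 2 or 3, r between assays was 0.490 or 0.504 and that between efficiency levels 0.565 or 0.537. Those fits covered 410 or 407 genes, since more genes passed the filter, so the values are not for the same 255 genes.

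**Figure D3:**
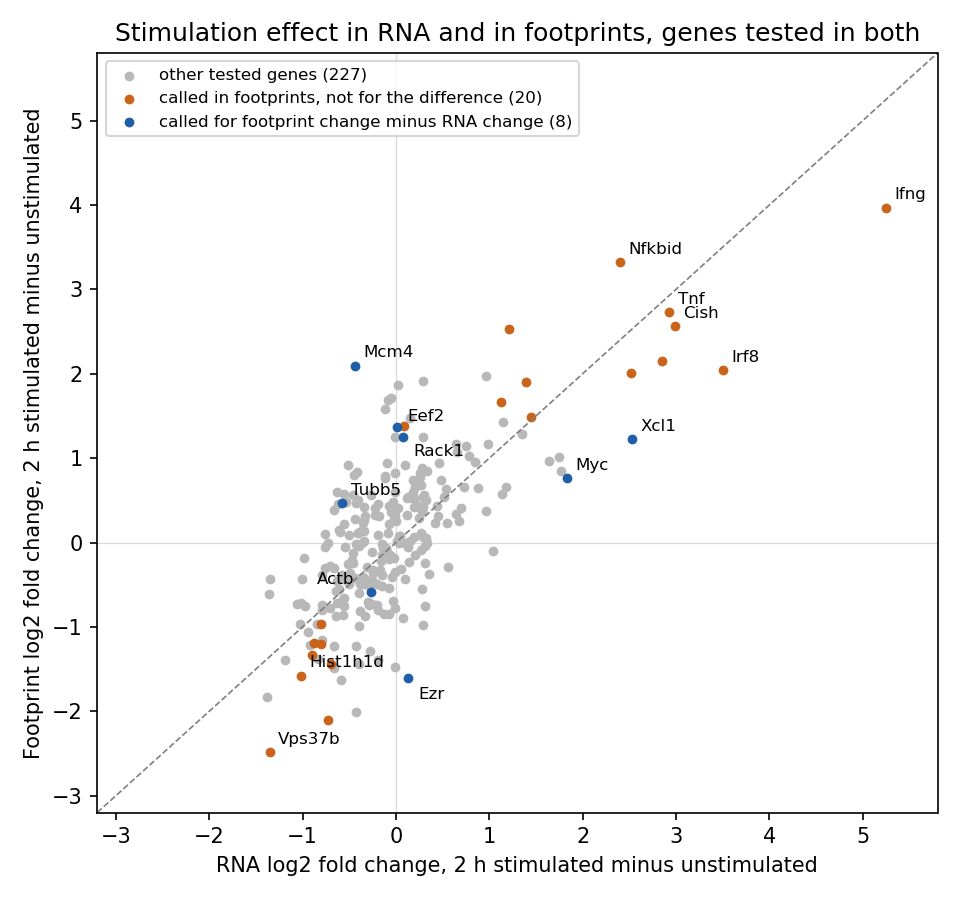
Footprint against RNA log2 change of the 255 genes tested in both assays, with the dashed line at equal change. The 8 genes called for the difference are blue, the 20 other genes called in footprints orange, and Ifng lies farthest to the upper right at 5.25 in RNA and 3.97 in footprints.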

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

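Of the tests in this part, the comparison of list sums, the restriction to genes of at least 10 CPM and the test on shared pseudogene reads were chosen only after the result was seen.

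For 8 genes the effect of stimulation differed between footprints and RNA by the interaction test of edgeR (255 genes tested, 3 unstimulated and 2 stimulated footprint libraries, 3 and 3 RNA libraries). The footprint change exceeded the RNA change by 2.43 on the log2 scale for Mcm4, which had 7 footprints before and 34 after stimulation, by 1.29 for Eef2, by 1.06 for Rack1 and by 0.90 for Tubb5. It was below the RNA change for Actb (-0.44), Myc (-1.18), Xcl1 (-1.39) and Ezr (-1.95). The p-values of this joint model may understate the footprint spread. None of the 8 passed in every fit that left out 1 library. Without unstimulated RNA replicate 1, 0 were called by edgeR, with 54 genes at an unadjusted p under 0.05 with all libraries. With all libraries limma voom called 0 of the 255 genes. DESeq2 called 29, over 10636 genes without edgeR's filter.

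Footprints of ribosomal protein and other TOP mRNAs took a larger share after stimulation, while their RNA sums did not pass the test on all genes. Among genes of at least 10 CPM both RNA sums passed as higher, by 0.18 and 0.25, with 56 of 81 and 20 of 24 genes higher, so a rise in RNA is not excluded as a part of the footprint rise. Thinning the footprints to the smallest total gave a rise of 0.70 in the ribosomal protein sum. Thinning keeps the expected share of each list, so it cannot decide whether libraries of unlike depth differ in other ways. The tables argue against the fall of histone footprints as the whole source. The ribosomal protein sum rose by 0.53 with histone genes left out of scaling, against 0.62 ± 0.13 before. Reads shared with pseudogenes stay open: ribosomal protein genes held 5.45 times as large a share of RNA as of footprints in unstimulated cells, and pseudogene reads that enter the RNA counts alike in both groups would dilute an RNA change. The footprint sum of ribosomal proteins passed in 11 of 12 alternatives. With the replicate block it did not pass (adjusted p = 0.0564), at a rise of 0.61 ± 0.09, and neither did that of the other TOP mRNAs (0.0822), at 1.19 ± 0.23 against 0.96 ± 0.23 before. The efficiency of the ribosomal protein sum, 0.41 ± 0.12, was 0.39 ± 0.14 without the 3 background-rich RNA libraries. That of the other TOP mRNAs went from 0.71 ± 0.16 to 0.70 ± 0.26. This setting left 1 stimulated RNA library, so only effects are given. The efficiency call of the ribosomal protein sum was lost without unstimulated footprint replicate 2 (0.0868). Without stimulated footprint replicate 2 or 3, with 1 stimulated footprint library left, that sum was at 0.40 or 0.41. A stronger loading of ribosomes on TOP mRNAs after activation remains a hypothesis, found and tested on the same data.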

How the results depend on the processing

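In this part the background covariate, the two-part settings on genes of at least 10 CPM, the scalings without 4 genes and the libraries with much background left out were chosen only after the result was seen.

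No named gene or list that was called changed to a call in the opposite direction in any alternative that was run. Of 109 RNA calls of named genes, 67 passed in every alternative and 70 in every fit without 1 library, and for footprints 3 and 7 of 24, for efficiency 0 and 0 of 8 (54 genes at an unadjusted p under 0.05, 29 by DESeq2, 0 by limma voom). The 1560 RNA genes became 2829 with DESeq2, 3387 with limma voom, 5220 with library totals, 5931 with the stricter filter, 628 at an adjusted p of 0.01, 3016 with the background covariate, 6228 among genes of at least 10 CPM, 6103 with scaling on those genes, 7341 without the 3 background-rich libraries and 6424 with that and at least 10 CPM. Thinned to the footprint depth and without stimulated replicate 1, to match the footprint libraries, RNA gave 17 calls of 176 genes. The fits without the 3 background-rich libraries kept 1 stimulated RNA library, so they hold no measure of spread among stimulated samples. Their counts therefore cannot show that more genes changed than in the main test. Leaving out 1 library gave 583 to 13024. DESeq2 and the setting with no filter took in 21427 genes in RNA, 10647 in footprints and 10636 for efficiency. Their counts are therefore not out of the same genes as in the main tests. The 24 footprint genes became 11 with DESeq2, 11 with no filter, 0 of 5 genes left by the stricter filter (edgeR), and 12 to 30 without 1 library. The 8 efficiency genes became 29 with DESeq2, 0 with limma voom, 15 with library totals, 4 with no filter, 0 of 5 genes with the stricter filter, 0 at an adjusted p of 0.01 and 0 to 9 without 1 library.

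Whether replicate numbers pair the samples could not be told. Same-numbered unstimulated and stimulated RNA libraries had r of -0.79, 0.64 and 0.73 across genes, taken as deviations from their group means. The signs followed which libraries held much background. The main axis of variation among the RNA libraries, 85.7% of it, had r = 0.98 with background. With replicate number as a block the RNA count was 2404, the footprint count 26 and the efficiency count 9, and with a block for each culture 2. Camera called 17 of 34 RNA lists, 8 up and 9 down. The number called was 0 with an estimated correlation and 1 with fry, the effector cytokines (0.0199). Among genes of at least 10 CPM it was 12 of 26 (9 up and 3 down). There 2 were called with an estimated correlation, effector cytokines up (0.0184) and cell cycle down (0.0205). Without 1 library 14 to 18 were called. The lists called in these settings are not always from the 17. In footprints camera called 4 lists, 3 up and 1 down, and 0 were called with an estimated correlation. Fry called 4, all up: it kept cytokines and transcription factors, lost other TOP mRNAs (0.111) and actin (0.0829), and added negative feedback (0.0226) and heat shock (0.0496). For efficiency 0 were called with an estimated correlation and 0 with fry, where camera called 1, and 0 to 1 without 1 library. The correlation of RNA and footprint changes ranged from 0.490 to 0.721 and that of efficiency levels from 0.537 to 0.799 without 1 library, over 255 to 410 genes. Unless stated, the cause was not tested. Where 1 stimulated footprint or RNA library was left, the lone sample was assumed to vary like the other groups. With 1 stimulated footprint library, 411 or 408 genes were tested in footprints, against 256 with both. A GC correction was not run, since no reference gave GC content, and a minimum of 100 counts in both assays left 1 gene.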

Other observations

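All tests in this part were chosen only after the result was seen.

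The footprints of the genes that changed in RNA moved as groups. The 677 RNA-raised genes took 4.43 ± 0.582% of unstimulated and 9.66 ± 0.168% of stimulated footprints (log2 change 1.05 ± 0.18, adjusted p = 0.00199), and the 883 RNA-lowered genes 9.73 ± 0.983 and 5.91 ± 0.0861% (-0.78 ± 0.12, adjusted p = 0.00158), calls that held in 12 of 12 alternatives. These sets were chosen on the RNA libraries themselves, so their RNA change and any efficiency computed from it are not independent evidence.

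Footprint sums rose for several lists whose members were mostly too sparse to test. The NF-kappaB pathway rose by 0.65 (adjusted p = 0.0104), lost without unstimulated replicate 2 (0.0876) or stimulated replicate 3 (0.118), and negative feedback regulators by 0.54 (adjusted p = 0.0171), lost without unstimulated replicate 3 (0.0784) or stimulated replicate 3 (0.257). With the replicate block neither passed (0.0591 and 0.135). Sums for heat shock genes (0.43, adjusted p = 0.0272) and the actin cytoskeleton (-0.42, adjusted p = 0.0327) passed too. The heat shock sum was lost without any 1 of the 5 footprint libraries (0.0516 to 0.269), with histone genes out of scaling (0.0654) and with the block (0.101). The actin sum was lost without stimulated replicate 2 (0.156) or 3 (0.300), with thinned footprints (0.0926), with library totals (0.0634) and with the block (0.0564). Csf2 went from 3 to 16 footprints and Il2 from 2 to 42, over 3 unstimulated and 2 stimulated libraries. In RNA, the sum of B cell markers rose by 0.70 (adjusted p = 0.0249), that of CD4 and regulatory T cell markers by 0.77 (adjusted p = 0.00368) and that of neutrophil markers by 1.44 (adjusted p = 0.000466), the last to 0.00158% of counts. Among the neutrophil and the B cell markers, as in the background genes, counts were highest in unstimulated replicate 2 and stimulated replicates 1 and 2. The B cell sum was lost without unstimulated replicate 1 (0.115) or 3 (0.313), or stimulated replicate 1 (0.218) or 2 (0.231) and with the block (0.0840), and the CD4 sum without unstimulated replicate 1 (0.0535) or 3 (0.116), or stimulated replicate 2 (0.153).

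A set of 16 genes outside the lists, all with an RNA log2 change of at least 3 and at least 10 CPM, had together fewer footprints than their RNA share would give, among them Lars2, Rps6ka2, 1810010D01Rik, Cep112, Hoxd11, Emp2, Sox12, Fam20a, Pou4f1, Axin2, Casr, Tmtc2, Adad1, Gadd45g and St5. Without Lars2 they held 23 stimulated footprints where their share of RNA would give 99.2, a ratio of 0.232 with an upper 95% Poisson limit of 0.348. Of the 99.2, Rps6ka2 (35.4), Axin2 (19.3), Cep112 (13.8) and Fam20a (10.3) carry the largest parts, and of these only Fam20a had stimulated footprints (4). Not every member was low: Gadd45g had 13 footprints against 6.17, Sox12 had 3 against 3.88, and many members expect too few to judge singly. Without Gadd45g as well the set held 10 against 93.0, a ratio of 0.107. In contrast, 7 list members with as large an RNA change held 274 against 136, so the tables argue against too few footprint counts. The set's median log2 change was 5.71 with the background covariate and 5.52 without it. The set was chosen for a large rise in the same libraries, so this refit cannot decide whether background reads took part. Lars2 alone had 0 stimulated footprints against 1936, an upper limit of 0.00191 for the ratio. Transcripts that are made but little translated, or reads from repeats or from transcription that runs past the ends of neighbouring genes, are candidate explanations that were not tested: Cep112, Axin2 and Fam20a lie between 108425215 and 109723163 on chromosome 11, and Adad1 lies next to Il2 on chromosome 3.

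The number of genes called in RNA varied with background reads. The 6 RNA libraries allow 10 splits into groups of 3, too few for a share under 0.05. Counting the real split, which called 1560 genes, 2 of the 10 called at least as many. The splits with fewer calls each called 0 genes, and the 1 other split called 3848. That split set the libraries with the most background (unstimulated replicate 2 and stimulated replicates 1 and 2) against the rest, so background may set the scaling and the spread behind the count. Among genes of at least 10 CPM the real split called 6228 genes by edgeR, and every other split, this one included, called 0. All other splits mix stimulated and unstimulated libraries in both groups, which widens the spread within groups. That 0 therefore cannot decide whether background took part in the 6228 calls. The median log2 change of the genes called higher was 1.14 with a background covariate and 0.99 without it. That of the background genes went from 1.25 to 0.16. The covariate is made from the counts of these same genes, so their drop does not test it. The genes called higher were chosen on the same libraries, so this refit cannot decide whether background took part. Of 1261 background genes, 1 was called higher. What the background reads are, genomic DNA for example, was not tested.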
